A study of Homo sapiens with 16 samples.

How the data were processed

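Polyadenylated RNA was sequenced from SW480 and SW620 cells that carried GFP or dnLEF1, with 4 libraries in each of 4 groups and 16 libraries in all. Per the labels' protocols, the cells were grown in DMEM, RNA was taken up in TRIzol and libraries were made with a TruSeq kit. The libraries of a group are separate samples, but the labels do not say whether they came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical.

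The deposited values are raw counts of reads per gene, made by the authors. Per the submitters' processing notes the tools were Trimmomatic, TopHat2, HTSeq and DESeq2, with the hg38 build. Versions, the gene annotation and the strand setting are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be told apart. Each file lists 26485 gene symbols, some of them older ones, and 5 summary lines that name no gene, in the format of HTSeq. Reads that aligned to more than 1 place are in a summary line and not in the gene counts, so members of gene families with near-identical copies are undercounted to an unknown degree. The summary lines held 20.0% to 24.3% of the total in 15 libraries and 50.5% in SW620 GFP replicate 3, and were left out of library sizes and tests. Gene counts came to between 17181204 and 26153506 per library. The 10 most abundant genes took 4.62% to 5.27% of them.

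Groups were taken from the labels. No pair of libraries within a group differed by as little as counting noise alone would give. The chi-square per degree of freedom was 1.99 to 22.2 over genes, so all 16 libraries were counted as separate samples. Replicates 2 and 3 were the closest pair in SW480 GFP, at 1.99, and in SW480 dnLEF1, at 2.33. The other pairs of either group were at 6.78 or more. Repeat preparations of a culture could also exceed counting noise, so this check does not show separate cultures. Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group, and the quasi-likelihood test with Benjamini-Hochberg adjusted p-values, called below 0.05. SW480 dnLEF1 against SW480 GFP, SW620 dnLEF1 against SW620 GFP, and the GFP libraries of the lines against each other were each fitted on their own 8 libraries. The difference between the lines in the dnLEF1 effect was tested as an interaction in 1 fit of all 16 libraries. Log2 fold changes are given ± an approximate standard error, the absolute log2 fold change over the square root of the test's F. CPM (counts scaled by the effective library sizes of the fit, unless another scale is named) are given as mean ± SD. The 2-fold counts are of called genes with a log2 fold change of at least 1 either way.

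For a gene with no count in any library of a group, a fold change was set against a floor of 3 counts over that group's 4 libraries and is a lower bound. For genes with 1 to 3 counts the ratio is given with its 95% exact Poisson interval. Floors and intervals cover counting error only.

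The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. There were 33 gene lists with 1114 entries, of which 1099 were matched to symbols in the files. They cover Wnt signalling, junctions, adhesion and motility, lineage, cell cycle, metabolism, stress and inflammation, and markers of other cell types and of RNA quality. Each list with at least 5 measured members was tested with camera (limma 3.58.1, inter-gene correlation preset at 0.01) against all other genes. Its adjusted p is over the lists of a comparison. Camera with a correlation estimated for each list, and fry, were alternatives. The count of members changed is given over all genes tested and also adjusted over the list alone.

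Genes are named by a rule. It takes LEF1, and the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 5 in 1 group and no overlap between the groups' libraries. It also takes up to 4 called members with the smallest adjusted p of each called list and of the lists for Wnt targets, adherens junctions, tight junctions, cell-matrix adhesion and actin. AXIN2, LGR5, NKD1, MYC, CCND1, CDH1, VIM and ZEB1 are taken whatever their values. For the interaction and the GFP comparison the rule takes the 6 largest each way, without the overlap condition for the interaction. Not every gene it takes is printed, and some are not reported here. Other members of lists are named only to say which members made up a count, unless said otherwise.

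Stretches of neighbouring genes that moved together were sought after such a shift had been noticed. Genes with a mean log2 CPM above 2 were placed on hg38 with GENCODE 44, which gave a position for 22923 symbols (86.6%). A stretch is a union of windows of 25 neighbouring genes of which at least 23 moved the same way. In 100 random orders of the genes, at most 6 such windows arose in either line, against 222 observed in SW480 and 424 in SW620.

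The alternatives were RLE and upper quartile scaling, other filters for low counts, DESeq2 1.42.0, limma voom with sample quality weights, the replicate number as a block, a fit of all 16 libraries, a minimum fold change and leaving out each library. Leaving out the genes of the stretches was added after the data were seen. The edgeR test, camera and the search for stretches were tested on simulated counts with the means and depths of the real libraries. The alternatives were not. In the simulated counts 200 genes were changed, 50 at each of 4 sizes. A list of 40 genes was also shifted by a log2 of -0.6 and a stretch of 120 genes by 0.35. These are a small part of the genes, while 48.5% were called in the real SW480 comparison, so the shares below may not carry over to it. In the simulated SW480 comparison 36% of 1.25-fold, 86% of 1.5-fold, 94% of 2-fold and 100% of 4-fold changes were called, and 6.79% of the calls were false. For SW620 the shares were 50%, 84%, 94% and 100%, with 6.89% false. For the interaction they were 12%, 56%, 78% and 86%, with 4.88% false, and for the GFP comparison 60%, 80%, 98% and 100%, with 6.69% false. Without scaling factors the median log2 difference of all genes in the GFP comparison would be -0.12 rather than -0.02. The medians of the other comparisons lay between -0.01 and 0.02 under each scaling tried, which were TMM, RLE, upper quartile and none.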

Results

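Gene expression was measured by RNA sequencing in 2 human colon cancer lines that were established from the same patient, SW480 from the primary tumour and SW620 from a lymph node metastasis. Both lines have high Wnt signalling through a truncated APC. Each line carried GFP, the mock control, or dnLEF1, a LEF1 that lacks the part that binds beta-catenin and so occupies Wnt target genes without activating them. The comparison asks how blocking Wnt output changes gene expression in each line, with adhesion, junction and motility genes in view. There were 4 libraries in each of 4 groups, all from passage 6. Gene counts ran from 17181204 in SW620 dnLEF1 replicate 2 to 26153506 in SW620 dnLEF1 replicate 3. Log2 CPM of 14926 genes correlated at 0.993 to 0.998 between libraries of a group, at 0.961 to 0.995 between the constructs of a line and at 0.864 to 0.900 between lines. The first principal component held 83.6% of the variance and the second 9.35%.

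LEF1, the gene the construct is made from, was higher in every dnLEF1 library than in any GFP library of the same line. The gene lies on chromosome 4 at 108047545 to 108168956 on hg38, minus strand. In SW480 it went from 53.7 ± 1.78 to 256 ± 50.6 CPM (SD, n = 4), a log2 change of 2.26 ± 0.12 (edgeR adjusted p = 2.37e-09). In SW620 it went from 3.23 ± 0.476 to 22.4 ± 2.30 CPM, a log2 change of 2.79 ± 0.12 (edgeR adjusted p = 7.94e-09). Counts per gene cannot separate reads of the construct from reads of the cells' own LEF1. On the scale of all 16 libraries the level gained was 194 CPM in SW480 and 19.8 CPM in SW620. In CPM, LEF1 in SW480 GFP libraries was 2.22-fold above that in SW620 dnLEF1 libraries. CPM are not scaled for transcript length and the construct is truncated, so this does not rank the groups by LEF1 molecules.

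**Figure D1:**
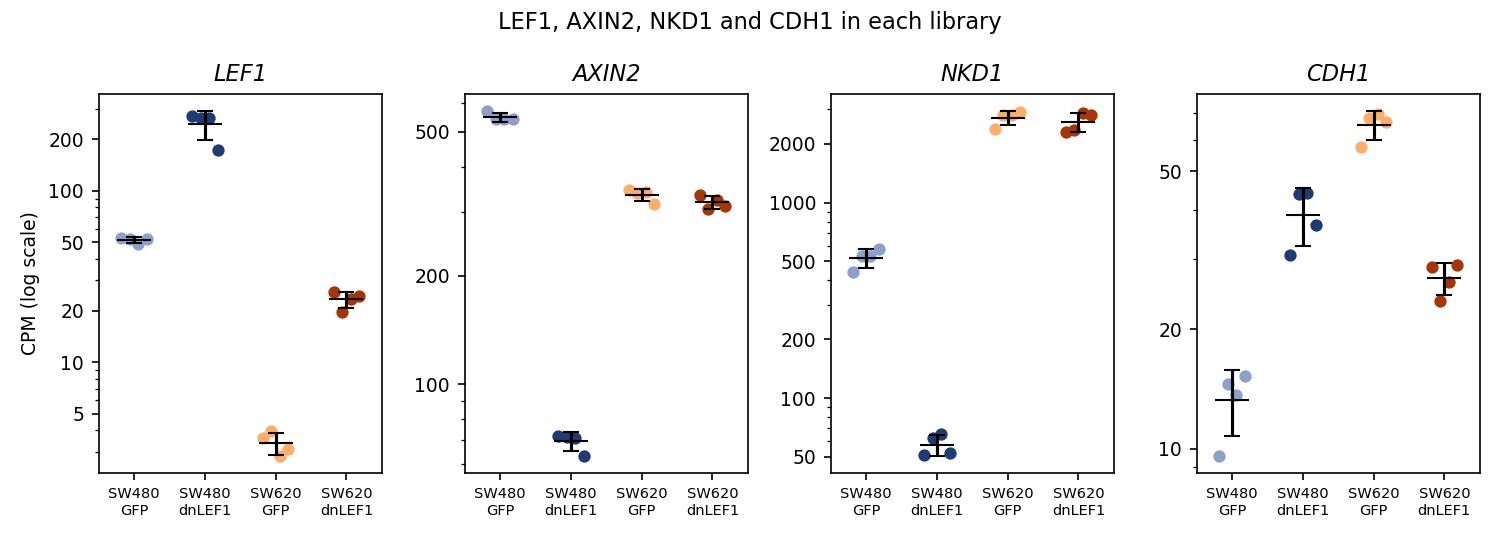
LEF1, AXIN2, NKD1 and CDH1 in each library, in CPM on a log axis scaled over all 16 libraries, with 4 points per group and the mean ± SD in black. LEF1 lay at 48.8 to 53.1 in SW480 GFP, 174 to 274 in SW480 dnLEF1, 2.85 to 3.97 in SW620 GFP and 19.7 to 25.6 in SW620 dnLEF1, while AXIN2 and NKD1 were lower with dnLEF1 in SW480 and CDH1 moved in opposite directions in the lines.

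In SW480, 29 of 41 measured Wnt target genes fell with dnLEF1 (camera adjusted p = 8.09e-27). AXIN2, a scaffold of the beta-catenin destruction complex and a feedback target of the pathway (chromosome 17, 65528563 to 65561648, minus strand), fell 7.87-fold. NKD1, which binds Dishevelled, had a log2 change of -3.17 ± 0.11. LGR5, the receptor that marks intestinal stem cells (chromosome 12, 71439798 to 71586310, plus strand), fell 11.5-fold. CDH1, which encodes E-cadherin (chromosome 16, 68737292 to 68835537, plus strand), rose 2.94-fold. Of 15 enterocyte genes 11 fell, and of 38 interferon response genes 26 rose, and their tests are given with each group.

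Of 14426 genes tested in SW480, 3485 rose and 3515 fell (edgeR adjusted p below 0.05), together 48.5%. Of these, 770 rose and 800 fell at least 2-fold. Neighbouring genes also moved together in 20 chromosome stretches, 9 higher and 11 lower in dnLEF1, which held 248 of the rises and 282 of the falls. On chromosome 5, 4 lower stretches between 53.6 and 150.4 Mb held 180 genes, 168 of them lower, with a median log2 change of -0.38. The longest ran from 90.5 to 131.8 Mb and had a median of -0.46. Whether gene length, GC content or differences between libraries lie behind the SW480 stretches was not tested.

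Of the 41 Wnt target genes measured in SW480, 29 fell, 5 rose and 7 did not pass the test, with a median log2 change of -0.86 (adjusted p = 0.000476 with an estimated correlation). Adjusted over the list alone, 31 fell and 5 rose. AXIN2 went from 572 ± 11.7 to 72.6 ± 4.49 CPM, a log2 change of -2.98 ± 0.07 (edgeR adjusted p = 1.22e-12). NKD1 went from 543 ± 63.6 to 60.4 ± 7.68 CPM, and LGR5 from 5.18 ± 1.22 to 0.445 ± 0.0978 CPM. The Wnt-inactivating hydrolase NOTUM had a log2 change of -3.33 ± 0.10, the Wnt inhibitor APCDD1 of -2.66 ± 0.09 and the transcription factor SP5 of -2.59 ± 0.08. CCND1, cyclin D1, fell 2.08-fold, to 1293 ± 76.3 CPM. MYC did not pass the test, at 247 ± 17.4 CPM with dnLEF1 and 239 ± 16.5 with GFP (log2 0.05 ± 0.07, edgeR adjusted p = 0.627). The 5 risen members were DKK1, FOSL1, PLAUR, MMP7 and JUN. BMP4, SLC12A2 and TCF7 among the fallen and FOSL1 among the risen lie in the stretches.

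**Figure D2:**
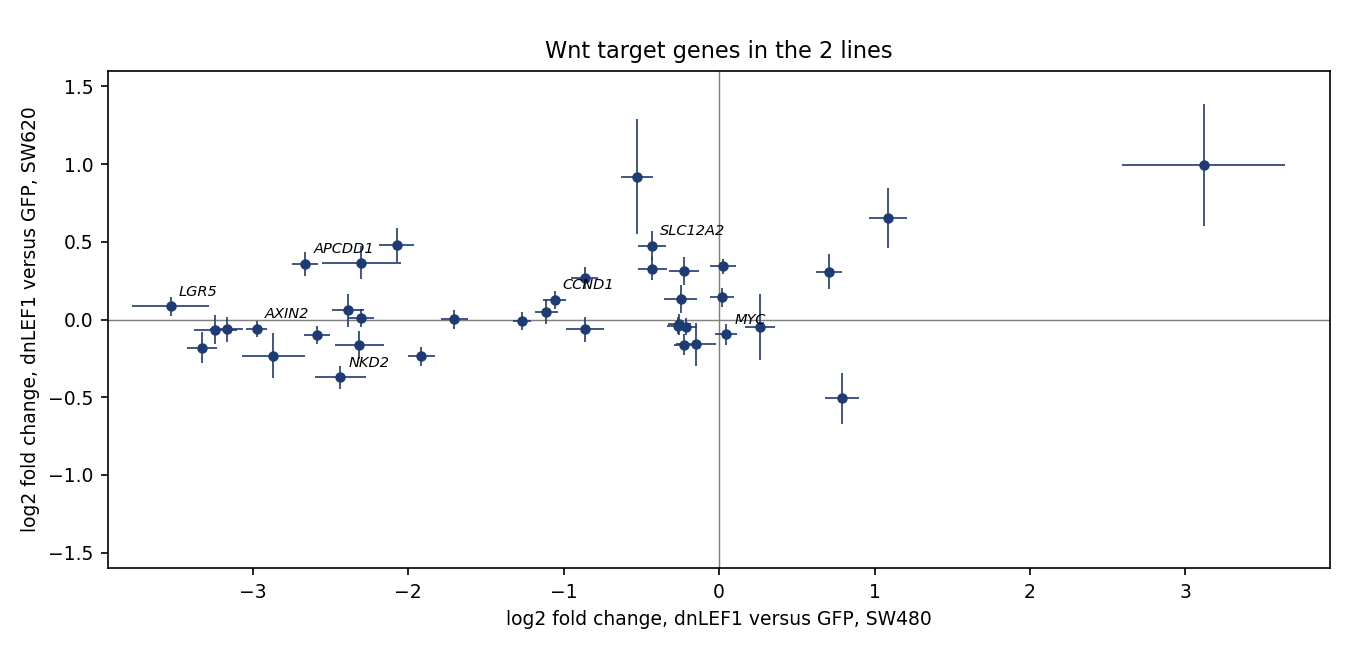
Log2 fold change (dnLEF1 versus GFP) of each Wnt target gene tested in both lines, SW480 on the horizontal and SW620 on the vertical axis, with bars of 1 standard error. Points spread along the SW480 axis, down to LGR5 at -3.53, and lie close to 0 on the SW620 axis, where AXIN2 was at -0.06 and NKD2 at -0.37.

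Junction genes of SW480 moved in both directions. Of 22 measured genes of adherens junctions and desmosomes, 6 rose and 11 fell (camera adjusted p = 0.730; the same counts adjusted over the list alone). CDH1 went from 13.8 ± 2.71 to 40.6 ± 6.94 CPM (log2 1.56 ± 0.15, edgeR adjusted p = 7.81e-07). The nectin gene PVRL3 (now NECTIN3) rose 6.12-fold and PERP, a desmosome-associated membrane protein, 2.37-fold. The alpha-catenin gene CTNNA1 fell 1.71-fold and the desmocollin gene DSC2 8.73-fold. CTNNA1 and the risen PVR lie in the stretches. Of 27 tight junction genes, 9 rose and 8 fell (camera adjusted p = 0.640; the same counts adjusted over the list alone), with a median log2 change of 0.15, a mean of -0.19 and a test directed downward. The claudin gene CLDN3 rose 2.32-fold, while the adhesion receptor gene CXADR fell 6.62-fold and the paracingulin gene CGNL1 29.0-fold. Of 10 gap junction genes, 3 rose and 5 fell (camera adjusted p = 0.367), also when adjusted over the list alone, and the fallen GJB1 lies in a stretch.

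Genes for contact with the matrix and for motility moved both ways in SW480. Of 37 cell-matrix adhesion genes, 16 rose and 9 fell (camera adjusted p = 0.549), also when adjusted over the list alone. The integrin gene ITGB8 rose 3.35-fold and ITGA1 fell 10.4-fold, from 128 ± 19.0 to 12.4 ± 1.42 CPM (log2 -3.38 ± 0.12, edgeR adjusted p = 2.19e-11). Of 59 genes of the actin cytoskeleton, 21 rose and 16 fell (camera adjusted p = 0.0883), with the same counts adjusted over the list alone. The calponin gene CNN3 rose 8.83-fold, the GTPase gene RAC2 3.51-fold and ENAH, which promotes actin elongation, 2.71-fold. In the stretches lie CD151 and VASP among these rises and FERMT2, DIAPH1 and DOCK1 among the falls. Of 34 extracellular matrix genes, 18 rose and 5 fell (camera adjusted p = 0.000802, but adjusted p = 0.477 with an estimated correlation), or 19 and 9 adjusted over the list alone. The fibulin gene FBLN1 rose 5.10-fold and the laminin gene LAMB1 2.10-fold, while the collagen gene COL4A2 fell 2.49-fold and the laminin gene LAMB3 2.28-fold. Of the 18 rises, LOX lies in a stretch, a lower one, against the direction of its rise.

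Of 16 measured EMT transcription factors and mesenchymal markers, 7 rose and 1, the protease gene MMP14, fell in SW480 (camera adjusted p = 0.0120, but adjusted p = 0.191 with an estimated correlation), with the same counts adjusted over the list alone. The call was lost in 8 of 14 alternatives, among them leaving out GFP replicate 1 (adjusted p = 0.0722) or any 1 of the 4 dnLEF1 libraries, with adjusted p up to 0.191. The matrix protein gene TGFBI rose 2.31-fold (log2 1.20 ± 0.09, edgeR adjusted p = 1.23e-07), the receptor kinase gene AXL 2.08-fold and VIM, vimentin, 1.53-fold. TGFBI and LOX, 2 of the 7, lie in lower stretches, against the direction of their rises. ZEB1, a repressor of E-cadherin, had a log2 change of 0.12 ± 0.12 (edgeR adjusted p = 0.431), although it passed without GFP replicate 1 and under limma voom.

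Among immunoglobulin superfamily, protocadherin and neural adhesion genes of SW480, 7 of 28 rose and 12 fell (camera adjusted p = 8.74e-06, but adjusted p = 0.142 with an estimated correlation), or 7 and 14 adjusted over the list alone. ALCAM, which encodes the adhesion molecule CD166 (chromosome 3, 105366909 to 105576900, plus strand), rose from 3.11 ± 0.457 to 21.6 ± 2.78 CPM (log2 2.80 ± 0.13, edgeR adjusted p = 6.02e-10). NCAM1 fell 4.52-fold. The protocadherin gene PCDH19 went from 41.5 ± 2.68 to 0.0800 ± 0.0931 CPM (log2 -8.93 ± 0.24, and -9.65 to -8.52 over the alternatives). PCDH9 had no count in any dnLEF1 library and 46.0 ± 13.1 CPM with GFP, at least 1353-fold lower. CNTN1 and PCDH1, 2 of the 12 falls, lie in stretches.

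Of 15 measured enterocyte genes in SW480, 11 fell and 2, ANPEP and SLC5A1, rose (camera adjusted p = 1.45e-07, but adjusted p = 0.191 with an estimated correlation), or 12 and 2 adjusted over the list alone, with a median of -0.76. CDX2, the intestinal homeobox factor (chromosome 13, 27960918 to 27969315, minus strand), went from 12.7 ± 0.657 to 0.137 ± 0.0640 CPM (log2 -6.48 ± 0.21, edgeR adjusted p = 1.77e-11). The microvillus gene VIL1 fell 14.3-fold and the keratin gene KRT19 1.70-fold. None of these falls lies in a stretch.

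Of 38 interferon response genes in SW480, 26 rose and 2, SAMD9 and OAS2, fell (camera adjusted p = 0.000503, but adjusted p = 0.365 with an estimated correlation), with a median of 0.51 and the same counts adjusted over the list alone. The antiviral GTPase gene MX1 rose 2.65-fold and the immunoproteasome gene PSMB9 2.58-fold. IFI35, IFITM1, IFITM3 and IRF7, 4 of the 26, lie in stretches. Of 19 NF-kB targets and chemokines, 12 rose and 2, CXCL8 and CXCL1, fell (camera adjusted p = 4.35e-05, but adjusted p = 0.191 with an estimated correlation), with the same counts adjusted over the list alone. The chemokine gene CCL2 rose 35.7-fold, from 0.237 ± 0.0847 to 8.80 ± 1.40 CPM, and the apoptosis inhibitor gene BIRC3 2.88-fold. The risen RELB lies in a stretch. Of 25 YAP and TEAD targets, 15 rose and 3, IGFBP3, YAP1 and GADD45B, fell (camera adjusted p = 8.74e-06, but adjusted p = 0.409 with an estimated correlation), or 15 and 4 adjusted over the list alone. CYR61 (now CCN1), a secreted matricellular protein gene, rose 3.85-fold and the tissue factor gene F3 5.21-fold, while IGFBP3 fell 4.38-fold. GADD45B lies in a higher stretch, against the direction of its fall.

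Of 45 nuclear genes of oxidative phosphorylation in SW480, 22 rose and the other 23 did not pass the test (camera adjusted p = 0.0281, but adjusted p = 0.966 with an estimated correlation), with a median of 0.18 and the same count adjusted over the list alone. ATP5G1 (now ATP5MC1), a subunit of ATP synthase, rose 1.53-fold and COX4I1, of cytochrome oxidase, 1.33-fold. COX8A and NDUFB10 lie in stretches. The call was lost in 6 of 14 alternatives, among them leaving out GFP replicate 4, dnLEF1 replicate 1 or dnLEF1 replicate 4, with adjusted p up to 0.966.

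The largest rises in SW480 included SRPX2, a secreted protein gene, at a log2 change of 7.15 ± 0.27 (edgeR adjusted p = 4.66e-11), and the Rab effector gene SYTL5 at 6.96 ± 0.31. Over the alternatives SRPX2 ran from 6.79 to 7.83 and SYTL5 from 6.58 to 7.56. GREM1, an extracellular inhibitor of BMP (chromosome 15, 32718004 to 32745106, plus strand), rose from 0.583 ± 0.0364 to 46.7 ± 3.71 CPM (log2 6.30 ± 0.12, edgeR adjusted p = 2.81e-13). Among the largest falls were genes close to 0 counts in all 4 dnLEF1 libraries. Besides PCDH9, the liver-intestine cadherin gene CDH17 was at least 204-fold lower, the tight junction scaffold gene MPDZ at least 411-fold and the proteoglycan gene LUM at least 220-fold. The GABA receptor gene GABRG1 had 1 count with dnLEF1 and 10.98 to 33.57 CPM in the GFP libraries, a ratio of 1991 (95% interval 357 to 78692). In all, 20 genes with at least 5 CPM in GFP had 3 counts or fewer over the dnLEF1 libraries, and all 20 were lowest in GFP replicate 1 among the GFP libraries. Without that library 3329 genes rose and 3374 fell.

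In SW620, AXIN2, NKD1 and LGR5 did not pass the test. Of 18 genes of adherens junctions and desmosomes 7 fell, among them CDH1, 2.41-fold, and JUP, which encodes plakoglobin, 1.57-fold (camera adjusted p = 3.86e-10). Of 23 cholesterol synthesis genes 9 fell (camera adjusted p = 2.31e-12, but adjusted p = 0.0695 with an estimated correlation). Of 8 secretory lineage genes 4 rose, with the granule protein gene CHGB 3.85-fold higher (camera adjusted p = 4.71e-06). Neighbouring genes on chromosomes 5, 7 and 20 were higher together.

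Of 13336 genes tested in SW620, 804 rose and 324 fell (edgeR adjusted p below 0.05), 8.46% of them, with 116 and 71 at least 2-fold. In SW620 GFP replicate 3, the summary line for alignments to more than 1 place held 39.4% of the total, against 7.61% to 9.46% in the other 15 libraries. Without this library 653 genes rose and 242 fell. Under limma voom 1133 rose and 578 fell. With the replicate number as a block 1149 rose and 676 fell, although the numbers were not taken to pair samples.

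The rises of SW620 clustered on chromosomes. Genes were higher with dnLEF1 in 5 stretches, on chromosome 1 from 16.4 to 21.8 Mb, chromosome 5 from 50.7 to 95.8 Mb, chromosome 7 from 56.1 to 139.0 Mb and from 139.6 to 158.8 Mb, and chromosome 20 from 0.271 to 17.6 Mb. Of the 515 genes used, 498 were higher, with a median log2 change of 0.34. The medians of the 5 were 0.20, 0.43, 0.36, 0.23 and 0.31. They held 366 of the 804 rises (45.5%) and 3 of the 324 falls. Lower stretches, also 5, held 173 tested genes and 11 of the falls. With the genes of all these stretches left out of the fit, 393 genes rose and 248 fell.

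**Figure D3:**
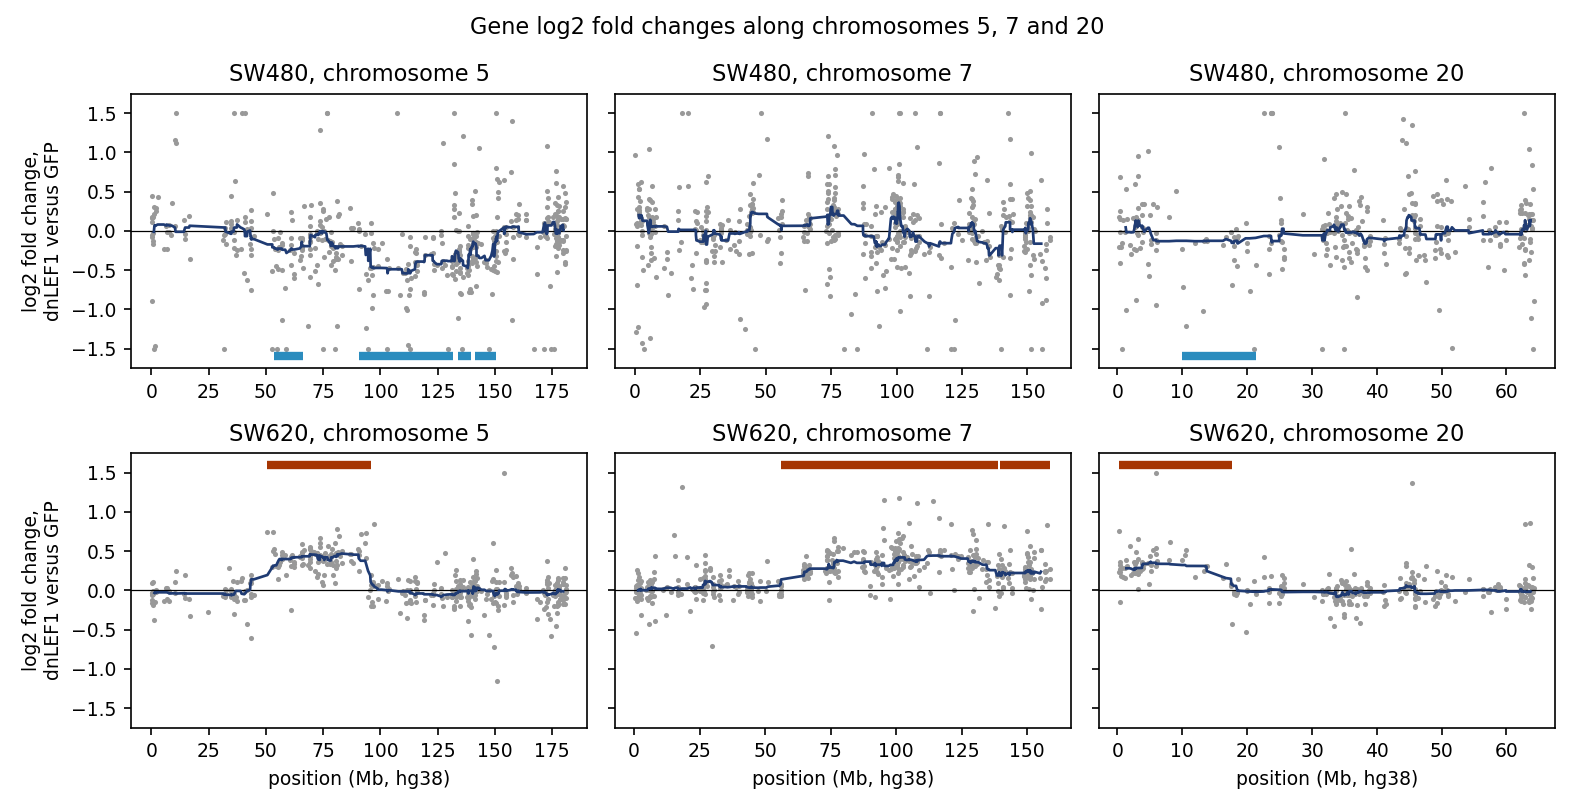
Log2 fold change (dnLEF1 versus GFP) of genes along chromosomes 5, 7 and 20 in Mb, SW480 above and SW620 below, with 1 grey point per gene, values beyond ±1.5 drawn at ±1.5, and the running median of 25 genes as a line. Bars mark stretches, higher at the top and lower at the bottom, and in SW620 the median steps up at their edges, to 0.43 on chromosome 5.

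Wnt target genes did not move as a group in SW620. Of 39 measured, 6 rose and 2 fell, with a median of 0.00 (camera adjusted p = 0.356), or 9 and 3 adjusted over the list alone. AXIN2 was at 307 ± 10.6 CPM with dnLEF1 and 320 ± 13.2 with GFP (log2 -0.06 ± 0.05, edgeR adjusted p = 0.607). NKD1 had a log2 change of -0.06 ± 0.08 (edgeR adjusted p = 0.746), LGR5 of 0.09 ± 0.06 (edgeR adjusted p = 0.497), MYC of -0.10 ± 0.07 (edgeR adjusted p = 0.507) and CCND1 of 0.13 ± 0.06 (edgeR adjusted p = 0.231, which passed under limma voom). NKD2, a paralogue of NKD1, fell 1.29-fold and ZNRF3 was the other fall. The transcription factor gene ETS2 rose 1.27-fold and the ion transporter gene SLC12A2 1.39-fold, and KIAA1549, in a stretch, had a log2 change of 0.33 ± 0.07.

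Of 18 measured genes of adherens junctions and desmosomes in SW620, 7 fell and 1, PERP, rose (adjusted p = 0.0290 with an estimated correlation), or 11 and 1 adjusted over the list alone. CDH1 went from 62.7 ± 5.02 to 25.9 ± 2.31 CPM (log2 -1.27 ± 0.08, edgeR adjusted p = 2.13e-07) and JUP (chromosome 17, 41754604 to 41786931, minus strand) from 103 ± 3.07 to 65.6 ± 3.97 CPM (log2 -0.65 ± 0.06, edgeR adjusted p = 7.86e-06). DSC2 fell 5.89-fold from a low level. CDH17 fell 3.23-fold, also from a low level, and did not pass in the fit of all 16 libraries (adjusted p = 0.0670). The other falls were PKP2 and PKP3, desmosome plakophilins, and CTNND1, which encodes p120-catenin. None of these 8 genes lies in a stretch.

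Of 24 tight junction genes in SW620, 5 rose and 3 fell (camera adjusted p = 0.934), or 7 and 5 adjusted over the list alone. The 5 rises, CLDN3, CLDN4, CLDN12, CLDN15 and OCLN, all lie in the stretches. OCLN, occludin, rose 1.42-fold. MARVELD3 fell 2.00-fold and F11R, which encodes junctional adhesion molecule A, 1.19-fold. Of 34 cell-matrix adhesion genes, 3 rose (camera adjusted p = 0.284), or 6 with 1 fall adjusted over the list alone: ITGA2, ZYX and FERMT1, all in the stretches. ZYX, the focal adhesion protein zyxin, rose 1.43-fold. FERMT1 did not pass in the fit of all 16 libraries (adjusted p = 0.0502). Of 58 genes of the actin cytoskeleton, 3 rose and 3 fell (camera adjusted p = 0.934), or 4 and 3 adjusted over the list alone, and CALD1 and LIMK1, 2 of the rises, lie in the stretches. FSCN1, fascin, fell 1.34-fold. Of 7 gap junction genes only the connexin gene GJC1 passed, with a rise from 5.06 ± 0.608 to 17.9 ± 1.58 CPM (log2 1.82 ± 0.11, edgeR adjusted p = 1.58e-07), also when adjusted over the list alone. The camera adjusted p of 0.00146 became an adjusted p of 0.0673 with an estimated correlation.

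Among 11 mesenchymal markers of SW620, 4 rose and 1 fell (camera adjusted p = 0.262), or 6 and 2 adjusted over the list alone. VIM rose 1.21-fold (log2 0.27 ± 0.06, edgeR adjusted p = 0.00749), but had an adjusted p of 0.0543 in the fit of all 16 libraries. ZEB1 had a log2 change of 0.32 ± 0.09 (edgeR adjusted p = 0.0344) and lost its call in 8 of 14 alternatives, among them leaving out any 1 library except dnLEF1 replicate 2, with adjusted p up to 0.123.

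The 23 genes of cholesterol synthesis and uptake had a median log2 change of -0.23 in SW620. Adjusted over the list alone, 15 fell and 1 rose. HMGCS1, which makes HMG-CoA, fell 1.52-fold (log2 -0.61 ± 0.06, edgeR adjusted p = 3.28e-05). NSDHL, another of the 9, lies in a lower stretch. Of 25 hypoxia targets, 7 fell (camera adjusted p = 0.000118, and adjusted p = 0.0290 with an estimated correlation), with a median of -0.19, or 11 with 1 rise adjusted over the list alone. The glucose transporter gene SLC2A3 fell 2.05-fold, from 41.8 ± 5.27 to 20.5 ± 1.84 CPM, and the adenylate kinase gene AK4 1.36-fold. The others were SLC2A1, HK2, EGLN3, PLOD2 and LOX, and none of the 7 lies in a stretch.

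Of 8 measured secretory lineage genes, 4 rose in SW620 (adjusted p = 0.0290 with an estimated correlation), with a median of 1.01, or 4 with 2 falls adjusted over the list alone. CHGB, chromogranin B of endocrine granules, went from 7.83 ± 1.02 to 30.3 ± 3.47 CPM (log2 1.95 ± 0.11, edgeR adjusted p = 6.54e-08) and lies in the chromosome 20 stretch. The tuft cell kinase gene DCLK1 rose 7.33-fold, the goblet cell gene AGR2 4.71-fold and the lysozyme gene LYZ 2.60-fold, each to less than 5 CPM. The log2 change of AGR2 ran from 1.95 to 2.91 over the alternatives.

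SCG2, which encodes secretogranin II of secretory granules (chromosome 2, 223596940 to 223602361, minus strand), rose from 2.06 ± 0.436 to 30.3 ± 2.57 CPM in SW620 (log2 3.88 ± 0.13, edgeR adjusted p = 3.80e-10). ISM1, in the chromosome 20 stretch, rose 14.4-fold and the hepatic lipase gene LIPC 4.72-fold. VAT1L (chromosome 16, 77788564 to 77980107, plus strand) had 3 counts over the GFP libraries and 6.19 ± 0.494 CPM with dnLEF1, a ratio of 184 (95% interval 62.5 to 893). Among the largest falls were ALCAM, from 12.9 ± 1.95 to 1.79 ± 0.303 CPM (log2 -2.85 ± 0.15, edgeR adjusted p = 6.01e-08), the ribosomal precursor RNA45S5, whose GFP level of 75.7 ± 54.7 CPM varied widely, the calpain gene CAPN6, 3.82-fold, and the receptor gene SORCS2, 3.38-fold. PRSS2, a trypsinogen gene that can share reads with its paralogues, had an uncertain log2 change of -2.02 ± 0.35. The neurotrophin receptor gene NTRK2 fell 2.80-fold and HKDC1, a hexokinase domain gene, 2.55-fold.

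The dnLEF1 effect on AXIN2, NKD1, LGR5, CDH1 and ALCAM differed between the lines. Each line was a separate experiment with its own controls, so a difference of line and of experiment cannot be told apart here. The log2 change of AXIN2 was 2.92 ± 0.08 higher in SW620 than in SW480 (edgeR adjusted p = 1.02e-15), that of NKD1 3.11 ± 0.14 higher and that of LGR5 3.62 ± 0.22 higher. CDH1, which rose in SW480 and fell in SW620, differed by -2.83 ± 0.18 (edgeR adjusted p = 1.66e-10), and ALCAM, with the same pair of directions, by -5.65 ± 0.21 (edgeR adjusted p = 5.02e-14). CCND1 differed by 1.19 ± 0.09. MYC, at -0.14 ± 0.10 (edgeR adjusted p = 0.346), and ZEB1, at 0.20 ± 0.16 (edgeR adjusted p = 0.368), did not pass. VIM differed by -0.34 ± 0.12 (edgeR adjusted p = 0.0392), a call lost in 11 of 21 alternatives, each of them leaving out 1 library, with adjusted p up to 0.0920. In this fit of 14926 genes, 2418 had a higher and 1830 a lower log2 change in SW620.

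Of 41 Wnt target genes, 26 had a higher change in SW620 and 2, PLAUR and DKK4, a lower one (camera adjusted p = 3.01e-41, and adjusted p = 1.21e-06 with an estimated correlation), or 29 and 4 adjusted over the list alone. Of 16 enterocyte genes, 10 were higher (camera adjusted p = 1.92e-08, but adjusted p = 0.0797 with an estimated correlation), or 11 and 1 adjusted over the list alone. Of 23 cholesterol genes, 15 were lower and 1 higher (camera adjusted p = 0.000108, but adjusted p = 0.524 with an estimated correlation), or 17 and 1 adjusted over the list alone. Adherens junctions did not pass as a list, with 4 of 22 higher and 6 lower (camera adjusted p = 0.410), or 6 and 7 adjusted over the list alone.

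Across the 12904 genes tested in both lines, 274 rose in both, against 174 for independent lists (one-sided Fisher's exact test, adjusted p = 3.88e-17), and 163 fell in both, against 76.1 (adjusted p = 3.31e-26). A rise in SW480 with a fall in SW620 was seen for 51 genes, against 70.9 (adjusted p = 0.998), and the converse for 192, against 187 (adjusted p = 0.456). Of the 680 genes called in both lines, 64.3% thus moved the same way. Without the genes of the stretches 316 moved the same way and 136 in opposite directions. DSC2 and SLC2A3 fell in both and GJC1 rose in both. Genes are not independent replicates, and the Fisher p-values take no account of genes that move together, as in the stretches. That test was not repeated without the genes of the stretches. Across genes the log2 changes correlated weakly (Pearson's r = 0.0839, Spearman's rho = 0.170). The lines have separate GFP libraries, so shared controls add nothing to this overlap.

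Between the GFP controls, SW620 had much less LEF1 and CCND1 and more LGR5, NKD1 and CDH1 than SW480. LEF1 was 15.4-fold lower in SW620, at 3.35 ± 0.497 against 51.6 ± 1.92 CPM (log2 -3.94 ± 0.10, edgeR adjusted p = 8.01e-14), and CCND1 9.40-fold lower. LGR5 was 18.6-fold higher, at 92.7 ± 3.67 against 4.99 ± 1.19 CPM (log2 4.22 ± 0.12, edgeR adjusted p = 2.71e-13), NKD1 5.15-fold and CDH1 4.88-fold higher. AXIN2 was 1.66-fold lower and MYC 1.40-fold higher. VIM was 1.34-fold lower, and ZEB1 did not pass (log2 -0.02 ± 0.11, edgeR adjusted p = 0.875). Several genes were present in a single line. GNG11, a G protein subunit gene, and CDH11, a mesenchymal cadherin gene, had no counts in SW620 GFP libraries and were at least 3789-fold and 1443-fold lower there, and WNT5A had 2 counts against 292 ± 19.7 CPM, a ratio of 12495 (95% interval 3459 to 1.03e+05). Conversely SW480 GFP libraries had no count of F5, the coagulation factor V gene, which was at least 508-fold higher in SW620. The imprinted gene PEG10 had 1 count there against 204 ± 14.7 CPM in SW620, a ratio of 18532 (95% interval 3326 to 7.32e+05).

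Of 14350 genes tested between the controls, 5413 were higher and 5786 lower in SW620 (edgeR adjusted p below 0.05), 78.0% of them. Per the series' design the lines were separate experiments, so a difference of line and a difference of experiment cannot be told apart in this comparison or in the interaction.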

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

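The tests of library labels, of precision and of the level of LEF1 below were chosen only after the results they bear on were seen.

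Wnt target genes had the smallest camera adjusted p of the lists for the difference between the lines (3.01e-41), with a median log2 change over all measured members of -0.86 in SW480 and 0.00 in SW620. Mixed-up labels are argued against, since LEF1 lay on its own construct's side of the line in all 16 libraries and 0 libraries were out of place. Lower precision in SW620 is also argued against, since 26 of all 41 members had a higher change in SW620 and 2 a lower one by the interaction test, 24 of the 28 that had been picked for their fall in SW480 differed, and the median standard errors of these 28 were 0.09 in SW480 and 0.07 in SW620. The level of the construct stays open: LEF1 RNA gained 9.77 times as much CPM in SW480 as in SW620, so a lower dose of dnLEF1 in SW620 and a different response to it cannot be told apart, because each line has a single level. How far dnLEF1 protein followed this RNA was not measured here. A difference between the experiments of the lines also stays open.

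Other lists also had a camera adjusted p below 0.05 for the difference between the lines, beside adjusted p-values above 0.05 with an estimated correlation. These were enterocyte genes (1.92e-08, and adjusted p = 0.0797 with an estimated correlation), cholesterol synthesis (0.000108 and 0.524), secretory lineage (0.00480 and 0.334), oxidative phosphorylation (0.010045 and 0.835), NF-kB targets (0.010045 and 0.334), immunoglobulin superfamily and neural adhesion genes (0.0108 and 0.358), extracellular matrix (0.0114 and 0.401), actin cytoskeleton (0.0152 and 0.524), YAP and TEAD targets (0.0152 and 0.524) and interferon response (0.0183 and 0.334). The counts higher and lower in SW620 were 5 and 1 of 14 secretory genes, 1 and 12 of 45 oxidative phosphorylation genes, 2 and 8 of 21 NF-kB targets, 9 and 5 of 30 adhesion genes, 3 and 12 of 36 matrix genes, 8 and 14 of 59 actin genes, 3 and 7 of 25 YAP targets and 3 and 13 of 38 interferon genes. Adjusted over the list alone they were 5 and 2, 1 and 15, 2 and 9, 10 and 5, 6 and 13, 9 and 16, 3 and 8, and 3 and 14. Without a filter the calls of the secretory, immunoglobulin superfamily, matrix and actin lists were also lost. With the replicate number as a block those of the immunoglobulin superfamily and actin lists were lost. The oxidative phosphorylation call was lost with fry, and the secretory lineage call without the genes of the stretches. Among lists not called for this difference, the median, the mean or the direction of the test differed in sign for Wnt pathway components, adherens junctions, cell-matrix adhesion, mesenchymal markers, TGF-beta and BMP, p53 targets, ribosome biogenesis, glycolysis, amino acid starvation, hypoxia and keratinocyte markers.

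Single genes that were followed in both lines differed in their log2 change with dnLEF1 by these amounts, SW620 less SW480: AXIN2 2.92, NKD1 3.11, LGR5 3.62, CCND1 1.19, CDH1 -2.83, ALCAM -5.65, SRPX2 -5.69, SYTL5 -6.12 and VIM -0.34. LEF1 itself differed by 0.53 ± 0.19 (edgeR adjusted p = 0.0431). That call was lost in 10 of 21 alternatives, limma voom and leaving out SW480 GFP replicate 1, 2 or 4, SW620 GFP replicate 1, 3 or 4, or SW620 dnLEF1 replicate 1, 3 or 4, with adjusted p up to 0.0980.

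Of 349 groups of 4 values tested, 25 had a library far from the other 3 by Dixon's criterion, where chance alone gives about 1 in 20. The CPM of this paragraph and the next are on the scale of all 16 libraries and differ from those of the fits. In SW480 GFP, AXIN2 was at 572 CPM in replicate 1 against 541 to 542, FERMT1 at 109 against 71.7 to 74.8 and LIMK1 at 123 against 135 to 136. ZYX was at 138 CPM in replicate 2 against 149 to 150.3, and replicate 4 had CHGB at 20.7 against 14.7 to 15.5 and RNA45S5 at 9.87 against 9.08 to 9.17. In SW480 dnLEF1, replicate 4 had LEF1 at 174 CPM against 266 to 274, together with AXIN2 at 63.5 against 71.1 to 72.0, PERP at 412 against 339 to 345 and GNG11 at 141 against 99.7 to 103. Replicate 1 of that group had CCND1 at 1137 CPM against 1262 to 1283, SLC2A3 at 217 against 284 to 297 and ETS2 at 90.8 against 83.1 to 83.8.

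In SW620 GFP replicate 3 the summary line for alignments to more than 1 place held 39.4% of the total against 7.94% to 8.71%. The ribosomal precursor RNA45S5 was at 165 CPM there against 45.4 to 54.8. Replicate 1 of SW620 GFP had PCDH9 at 6.25 CPM against 8.71 to 8.97, FSCN1 at 362 against 268 to 282 and SLC2A3 at 51.6 against 40.4 to 41.7, and replicate 4 had LYZ at 2.34 against 0.793 to 0.945. In SW620 dnLEF1, PSMB9 was at 2.67 CPM in replicate 1 against 1.62 to 1.74 and NKD2 at 55.9 against 61.3 to 62.3. SYTL5 was at 3.79 CPM in replicate 2 against 4.80 to 4.85, ZYX at 117 against 107 to 108 and PEG10 at 195.5 against 222 to 226, while PCDH9 was at 9.18 in replicate 3 against 7.09 to 7.37.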

How the results depend on the processing

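Leaving out the genes of the stretches was chosen only after the data were seen. No called result reversed its direction. With a minimum of 2-fold, 1570 genes were called in SW480, 187 in SW620, 1264 in the interaction and 4167 between the GFP controls, and the overlap was 47 genes in the same and 27 in opposite directions; fewer genes can pass by construction. In SW620, limma voom called 1711 genes against 1128, and the cause was not tested. Without the genes of the stretches it was 641, and the overlap in opposite directions 136, since many calls lie there. Lists called with an estimated correlation were 1 in SW480, 3 in SW620 and 1 in the interaction. With fry, which does not set a list against other genes, they were 15 in SW480 and 18 in the interaction. Without a filter 7 interaction lists were called, and the cause was not tested. With the replicate number as a block 1825 genes were called in SW620, and the overlap was 715 and 385. Same-number correlations were 0.22, -0.00, -0.07 and 0.04 in SW480 and 0.25, -0.00, 0.12 and 0.15 in SW620, and since not every one was over 0.1, the numbers were not taken to pair samples. As a hint from the data, 3 of 4 numbers in SW620 and 1 of 4 in SW480 correlated best with their own. Leaving out 1 library gave 5989 to 7007 genes in SW480, 810 to 1202 in SW620, 3614 to 4545 in the interaction and 10868 to 11381 between the controls. Lists ranged from 7 to 10 in SW480, from 5 to 10 in SW620 (10 without dnLEF1 replicate 1, 8 without GFP replicate 4) and from 11 to 13 in the interaction. LEF1 changed by 2.20 to 2.39 in SW480 and 2.72 to 2.87 in SW620, and the overlap was 315 to 494 genes in the same and 188 to 250 in opposite directions. Under the other settings counts of changed genes were 6432 to 7723 in SW480, 1064 to 1309 in SW620, 3450 to 5309 in the interaction and 10575 to 12472 between the controls. Of named genes, 1939 results under alternatives kept their side of the threshold, 32 lost the call and 3 gained it. For lists it was 1428, 40 and 54. Among those that kept their side, 81 of lists and 2 of genes changed sign, none called either way; the 2 were ZEB1 between the controls, at 0.09 with limma voom and 0.12 without SW480 GFP replicate 1. In the simulated SW480 comparison, where far fewer genes were changed than were called in the real one, the smallest changes were mostly missed (36% called).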

Other observations

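The tests of the same genes in SW480, of depth and of a population of cells below were chosen only after the results they bear on were seen.

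Beyond the groups described so far, cell cycle genes of SW480 moved little as lists. Of 42 DNA replication genes 14 fell and 3 rose (camera adjusted p = 0.481; 14 and 3 also adjusted over the list alone), and of 46 mitosis genes 12 fell and 5 rose (camera adjusted p = 0.805; 11 and 5 adjusted over the list alone), with BUB3, DLGAP5, KIF20A, KIF4A and MKI67, 5 of the 12, in stretches. Of 48 Wnt pathway components 17 rose and 19 fell (0.964), of 40 axon guidance genes 14 and 14 (0.962), of 27 Notch genes 6 and 11 (0.0883), of 38 TGF-beta and BMP genes 14 and 13 (0.360), of 13 secretory genes 4 and 7 (0.101), of 28 CDK inhibitors and p53 targets 7 and 6 (0.964) and of 31 growth factor response genes 7 and 8 (0.964), with camera adjusted p in parentheses. In metabolism and stress, 6 rose and 8 fell of 50 ribosome biogenesis and MYC targets (0.989), 12 and 8 of 34 glycolysis genes (0.805), 9 and 2 of 23 cholesterol genes (0.274), 7 and 9 of 30 amino acid starvation genes (0.489) and 8 and 9 of 26 hypoxia targets (0.360). Of markers of other cell types, 3 rose and 1 fell of 6 for blood and endothelium (0.561), 4 and 3 of 8 for keratinocytes and other carcinoma lines (0.762), and 4 of 10 replication-dependent histones rose (0.322). Fibroblast markers had 4 measured members and were not tested as a list, and no mitochondrially encoded symbol was in the files. Adjusted over the list alone, the rises and falls were 17 and 19, 15 and 15, 6 and 12, 14 and 13, 4 and 7, 7 and 6, 7 and 8, 4 and 6, 12 and 9, 9 and 2, 7 and 9, 8 and 10, 3 and 1, 4 and 3, and 4 and 0 in the order given from Wnt pathway components on. Among lists that were not called in SW480, the median, the mean or the direction of the test differed in sign for Wnt pathway components, tight junctions, axon guidance, TGF-beta and BMP, p53 targets, glycolysis, growth factor response and keratinocyte markers.

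In SW620 the remaining lists had few calls. Of 39 Wnt pathway components 3 rose and 4 fell (camera adjusted p = 0.187), of 25 matrix genes 4 and 5 (0.811), of 23 immunoglobulin superfamily and neural adhesion genes 3 and 2 (0.807), of 36 axon guidance genes 5 and 5 (0.581), of 25 Notch genes 3 and 3 (0.996), of 32 TGF-beta and BMP genes 2 and 2 (0.934) and of 34 glycolysis genes 1 and 3 (0.108). Falls alone were seen for 2 of 12 enterocyte genes (0.178) and 2 of 30 amino acid starvation genes (0.108). Rises alone were seen for 3 of 31 interferon genes (0.368), 5 of 31 growth factor response genes (0.232) and 5 of 21 YAP targets (0.265). All the rises lay in stretches for 3 of 42 DNA replication genes (0.325), 2 of 46 mitosis genes (CCNB1 and CDC25B; 0.745), 1 of 28 p53 targets (PLK2; 0.934), 1 of 50 ribosome biogenesis genes (UTP15; 0.356) and 2 of 45 oxidative phosphorylation genes (COX7C and NDUFA5; 0.996). With edgeR 0 of 19 NF-kB targets passed (0.934), while 2 rose and 3 fell at an unadjusted p below 0.05, 1 rose by DESeq2, and 1 rose and 1 fell by limma voom. For 11 histone genes edgeR called 0 (0.934), with 1 rise and 1 fall at an unadjusted p below 0.05 and 0 calls by DESeq2 and by limma voom. Adjusted over the list alone, YAP targets had 6 rises and 1 fall, matrix genes 5 and 5, adhesion genes 4 and 2, axon guidance genes 5 and 7 and Notch genes 4 and 4, and the other lists of this paragraph had the counts given. Among lists that were not called in SW620, the median, the mean or the direction of the test differed in sign for actin, Notch, TGF-beta and BMP, p53 targets, oxidative phosphorylation, NF-kB targets and growth factor response.

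A few genes were chosen after their values were seen. In SW620, EGFR, the epidermal growth factor receptor, rose from 0.115 ± 0.117 to 1.55 ± 0.395 CPM (log2 3.73 ± 0.47, edgeR adjusted p = 0.000158), and EREG, which encodes its ligand epiregulin, from 1.55 ± 0.136 to 5.25 ± 1.29 CPM (log2 1.76 ± 0.19, edgeR adjusted p = 4.47e-05). KRT5, a keratin of basal epithelia, was on the scale of all 16 libraries at 2437 ± 330 CPM in SW480 GFP and 862 ± 47.3 in SW480 dnLEF1 (log2 -1.495 ± 0.10, edgeR adjusted p = 1.77e-08), against 1.70 ± 0.530 in SW620 GFP. The Paneth cell defensin genes DEFA5 and DEFA6 rose in SW480 by a log2 of 3.86 ± 0.30 (edgeR adjusted p = 1.13e-07) and 5.77 ± 0.54 (edgeR adjusted p = 8.38e-07). DEFA6 had 3 counts or fewer over the GFP libraries, so the size of its rise is uncertain. With such members set at the floor of 3 counts, no secretory lineage gene of SW480 exceeded a log2 change of 5.51. Both values are also uncertain because reads that paralogues share are not in the gene counts.

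The stretches of chromosomes 1, 5, 7 and 20 that were higher in SW620 dnLEF1 stood out in each dnLEF1 library, with a median log2 value of 0.33 to 0.37 above the GFP mean on chromosome 7 from 56.1 to 139.0 Mb against -0.01 to 0.01 in the GFP libraries. Gene length and GC content are argued against, since the median stayed at 0.361 (quartiles 0.25 and 0.47) over 515 genes after their trend was taken off. A response shared by both lines is argued against, since the 498 of these 515 genes that were used in SW480, whatever their direction in SW620, had a median of -0.0328 there. A difference in copy number between the SW620 populations stays a candidate explanation. In the stretches, 120 lower expressed genes, which took no part in finding them, had a median of 0.401, against 0.04 for 2473 elsewhere. The shift thus extends to lower expressed genes of the same stretches. A response of whole stretches to dnLEF1 in SW620 alone would raise these genes too, so they cannot tell it from copy number. No DNA was measured here, and such a response stays open and untested.

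The 20 genes at 3 counts or fewer over the SW480 dnLEF1 libraries would have given a median of 631 counts at their GFP level. Depth thus does not account for them, but the limit of 5 CPM in GFP that picked them fixed this outcome. For the set, loss of DNA blocks reaching the nearest expressed genes is argued against by a median log2 change of -0.13 over 40 neighbours. The neighbours' starts lay 116418 to 10536261 bases from those of the genes, so only losses of such lengths could show. Some neighbours are counted for 2 genes, and 1 of the 40, DACH1, 5135132 bases from PCDH9, was below -1, at -3.35. Losses too short to reach a neighbour were not tested. All 20 genes were lowest in GFP replicate 1, with PCDH9 at 29.4, 46.9, 46.3 and 61.0 CPM in replicates 1 to 4. The CPM of this paragraph are scaled over the SW480 libraries alone. The median log2 deviation of the 20 in replicate 1 was -0.70. It was -0.01 for 5851 other genes with a similar range of CPM and -0.07 for the 29 fallen Wnt target genes. Of these 29, NKD1 had the same lowest and highest library as PCDH9, at 457, 554, 555 and 604. AXIN2 did not, at 592, 564, 564 and 563. A population of cells in the SW480 GFP samples that the dnLEF1 samples lacked and a response to dnLEF1 itself cannot be told apart: the shared lowest library had been seen before it was made a test, so it supports neither, and the same holds for the test it replaced, by the number of genes gained in the opposite direction, which was 1 against 20 lost.

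Other splits of the same libraries bear on chance. The real split gave 7000 genes in SW480, 1128 in SW620 and 11199 between the controls, and in each case 1 of 35 splits, the real one, gave as many, with 0 as the highest other. For the interaction it was 1 of 100 drawn splits, with 4248 genes and 3066 as the highest other. In the sets of 35, every other split mixes the groups compared, and 1 of 35 is the smallest share possible. For the interaction, the split with the labels of 1 line swapped was left out of the draw. Other draws could keep the real groups of 1 line and mix only those of the other. A high value in another draw therefore need not be chance, and whether the draw with 3066 genes was of this kind was not examined. A chance difference between cultures cannot be excluded this way, since the labels do not say whether a group came from separate cultures. For the number of lists called, a chance split cannot be excluded either. At least the 9 lists of SW480 came from 12 of 35 splits (highest other 14). At least the 5 of SW620 came from 24 of 35 (highest other 17). At least the 11 of the interaction came from 8 of 100 (highest other 14). List by list, the splits with an unadjusted camera p as small as the real one, which is counted among them, differed widely. In SW480 they were 22 of 35 for oxidative phosphorylation, 9 for interferon response, 5 for extracellular matrix, 3 for YAP and TEAD targets, 2 for NF-kB targets and 1 for each of the other 4 lists called. In SW620 they were 1 of 35 for each of the 5, though another split gave cholesterol synthesis a camera adjusted p of 2.25e-09. For the interaction they were 48 of 100 for oxidative phosphorylation, 35 for cholesterol synthesis, 24 for interferon response, 20 for YAP and TEAD targets, 10 for extracellular matrix, 8 each for actin and NF-kB targets, 2 each for Wnt targets, enterocyte genes and the immunoglobulin superfamily list and 1 for secretory lineage. Some lists have an estimated correlation far above the preset 0.01, as high as 0.68 for cholesterol synthesis in SW480, and whether this or a structure among the libraries lies behind the lists called in other splits was not tested.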
